A study of Mus musculus with 32 samples.

How the data were processed

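Gene expression was measured on 32 single-sample Affymetrix arrays. The RNA came from 8 mm punches of dorsal skin and ear of NC/Nga mice, kept in RNAlater for at least 18 hours, and 100 ng per sample was labelled with biotin. The series names the assay as Mouse Clariom D. The labels give 2 agents, sham and HDM, and 2 tissues, so that 4 groups of 8 mice result. Mouse numbers recur in back skin and ear, and the labels do not say whether such samples come from the same animal. The 4 groups may therefore hold fewer than 32 animals. The labels do not spell out HDM and do not describe the sham treatment.

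The deposited values are log2 expression levels that the authors made with RMA, a background correction, quantile normalization and summary per probe set, in the Transcriptome Analysis Console, per the submitters' processing notes. The versions of these tools, the genome build and the annotation release are not given in the sources used here, and chromosomal positions were not used. The values run from 1.71 to 19.93, and 12 tested rows reached 19.9 on at least 1 array, so differences between very bright signals near that limit may be compressed. The range is wide for RMA values, and whether they were rescaled after RMA could not be told from the files. If they were, the log2 differences and the folds given here would not be true ones, while directions would hold. Array medians of the tested rows lay between 5.91 and 6.26.

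Of the 28846 rows in the table, 6640 are array controls, and these were left out of the tests. They comprise 5222 negative control rows, 1324 positive control rows, 71 spike-in rows and 23 background probe rows. The plan fixed before the data were examined said all rows of the table, and leaving out the controls was decided once they had been seen. The 22206 remaining rows are transcript clusters, and whether they are all or only a part of those on the named array could not be told from the files. A gene symbol could be attached to 19572 of them, for 19505 genes. Values of 142 rows were identical on all arrays to those of an earlier row. Where several rows carried 1 symbol, the row with the highest mean over all arrays stood for the gene. Families of near-identical genes, among them Sprr2, Stfa, Serpinb3, Mup and Krtap, may share probes, so that values of single members are uncertain.

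The background of an array was taken as the median of its negative control rows, which ranged from 4.43 to 5.38. A gene below that level on all 8 arrays of a group was treated as below background there. Against such a group only a lower bound of the fold is given, as "at least N-fold", with the background level standing in for the value, and no fold is given where both groups lie below background. A gene above background on only some arrays of a group keeps its measured difference. Where the group mean then lies under the mean background of the group, the size is uncertain, and the difference with values under background raised to it is given beside it, a choice made after the results were seen. The number of arrays limits the precision of every value.

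Group means were fitted to the log2 values of all 32 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided moderated tests, 32.1 total degrees of freedom), with no covariate and no block. The 4 comparisons were HDM minus sham in back skin, HDM minus sham in ear, the difference between these effects (ear minus back), and sham ear minus sham back. Rows were called at a Benjamini-Hochberg adjusted p under 0.05 over the 22206 rows. Values are given as the difference ± its standard error, group values as the mean ± SD, with n = 8 mice per group throughout. The standard error rests on a single spread per row, pooled over all 4 groups and taken as equal in them. HDM ear spread more widely than sham ear for many inflammatory and epidermal genes. For these, errors and p-values in ear may be too small and those in back skin too large.

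Before the data were examined, 33 gene lists were fixed, covering inflammatory pathways, epidermal barrier and lipid genes, cell cycle, matrix, itch, clock and Hox genes, and markers of the cell types that a skin or ear punch can hold. They name 609 measured genes. Lists were tested with limma camera at a preset correlation of 0.01 between genes, adjusted over the 99 tests of the first 3 comparisons and over the 33 tests of sham ear against sham back. Camera with an estimated correlation and fry were the alternatives. Of the lists called with the preset correlation, 0 of 10 in back skin, 0 of 19 in ear, 0 of 19 for the difference between sites and 3 of 16 for sham ear against sham back held with an estimated correlation. Fry tests whether the genes of a list move, on balance, in 1 direction and compares them with no other genes. With fry, 112 of 132 list results stayed on the same side of the threshold, 7 calls were lost and 13 were gained. Every list called in back skin and in ear also passed with fry, so the lost calls lay in the other comparisons. Among the gained calls were itch genes in back skin (fry adjusted p = 0.00978) and in ear (0.000804). List medians are also given with genes below background in 1 group at their bound and genes below background in both at 0, where this moves a median that is printed for back skin, ear or sham ear against sham back. Medians of the difference between sites and those under alternatives carry no such bound and rest on the measured values.

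Genes were named by a rule fixed at the same time. In each HDM comparison it takes the 6 genes with the largest difference in each direction among called genes for which every HDM array lay on that side of the sham mean, a set of cytokine and epidermal genes whatever their result, and up to 2 members of each list with the smallest p. For the difference between sites and for sham ear against sham back it takes the 5 largest in each direction. Predicted genes, Rik clones and small RNAs were left out. The rule also names Krt6a and Flg, which were not analysed here.

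The procedure was tested on simulated data. Of 50 rows shifted by 1 on the log2 scale in one group of 8, 38 were recovered in back skin and 41 in ear. At a shift of 0.5 the counts were 5 and 9, at 2 they were 47 and 49, and at 4 all 50 were recovered at both sites. Over all rows that were not shifted there were 5 false calls in the back skin run and 8 in the ear run. The simulated noise was independent between rows and equally wide in all groups. The real arrays hold correlated genes and groups of unequal spread, so these counts do not give the error rate there. Other choices named beforehand were quantile normalization of the deposited values, equal array medians, a filter on dim rows, eBayes with trend and robust, array weights, fits within 1 tissue or agent, mouse as a block, covariates for muscle and adipocyte content and for hair, a minimum log2 difference of 1, 1 row per gene, and leaving out each array in turn. Choices made after seeing the data were the control rows included, sham back mice 1 and 2 left out, identical rows counted once, and the negative control median as a covariate. The mixed model used statmod 1.5.0.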

Results

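Expression in back skin and ear of NC/Nga mice, an inbred strain prone to dermatitis, was compared between sham and HDM animals on 32 arrays, with 8 mice in each of the 4 groups. Correlations of an array with the mean of the other arrays of its group were between 0.975 and 0.994. The share of rows above the negative control median of the array was between 54.4% and 62.3%. The first principal component held 42.5% of the variance and separated back skin from ear, and the second held 26.2% and separated HDM from sham arrays. Within sham back skin, the arrays of mice 1 and 2 stood apart from the other 6. On the genes of the hair follicle list their means were 6.69 and 10.69, against 11.45 to 15.27 on the others, and on the antimicrobial list 9.25 and 9.44, higher than on any other array of that group. Within HDM ear, mice 1, 2, 5 and 7 lay between 99.3 and 134 on the second component, and mice 3, 4, 6 and 8 between 6.79 and 39.5.

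**Figure D1:**
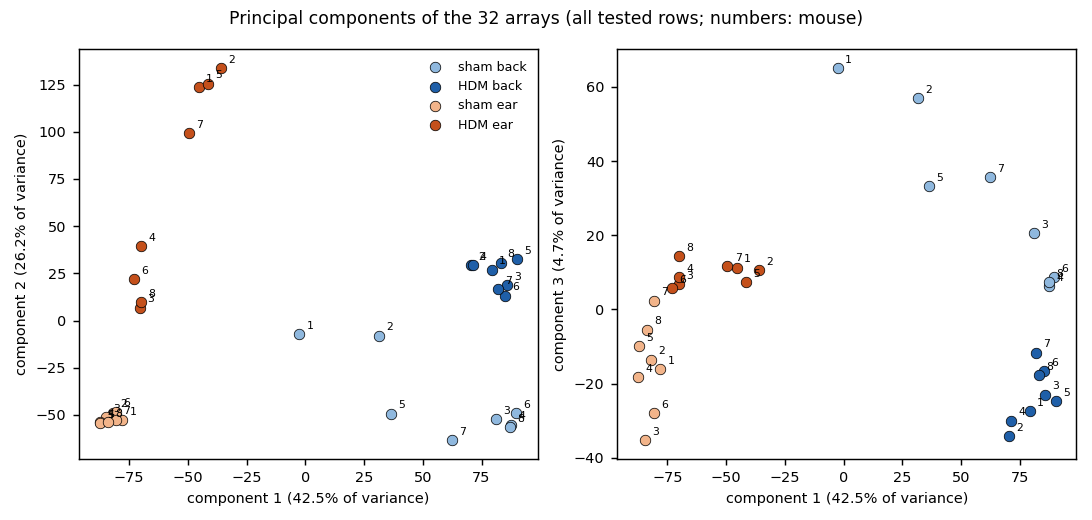
Scores of the 32 arrays on principal components 1 and 2 (left) and 1 and 3 (right), each point an array numbered by mouse and coloured by group. Component 1 (42.5% of variance) parts back skin from ear, and on component 3 (4.68%) the sham back arrays of mice 1 and 2 have the highest scores, 65.1 and 57.0.

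HDM against sham in back skin asks what the agent did to dorsal skin. The genes named for the largest rises encode calprotectin subunits, a beta-defensin, a chemokine and proteases. S100a9 and S100a8, which encode the subunits of calprotectin, rose by 8.57 ± 0.84 and 7.69 ± 0.79 on the log2 scale (adjusted p = 1.49e-08 and 3.30e-08), S100a9 from 9.31 ± 2.90 in sham to 17.88 ± 0.49 in HDM mice. Defb3, a beta-defensin gene, rose by 7.30 ± 0.69 (adjusted p = 7.24e-09) and Cxcl5, a chemokine that attracts neutrophils, by 6.92 ± 0.99 (adjusted p = 7.80e-06). The keratin gene Krt77 fell by 9.93 ± 0.78 on the log2 scale (adjusted p = 1.29e-10), from 17.48 ± 0.55 to 7.55 ± 2.87, and the cytochrome P450 gene Cyp2g1 fell by 7.84 ± 0.66 (adjusted p = 6.01e-10). Klk14, a kallikrein-related peptidase gene, rose by 7.89 ± 0.62 and Tmprss11b, a membrane serine protease gene, by 6.76 ± 0.72. Among serine protease inhibitor genes, Serpinb6d fell by 7.00 ± 0.55 and Serpina3b by 6.31 ± 0.66, and Serpina3j was at least 22.5-fold lower. For each of these genes all 8 HDM arrays lay on that side of the sham mean. Of the sham arrays 2 of 8 were above background for Cxcl5 and 2 for Tmprss11b, and with values under background raised to it the differences were 6.24 and 6.36.

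Of 26 measured stress keratin and small proline-rich protein genes, which are induced in injured and inflamed epidermis, 23 rose and 0 fell, the same counts as when adjusted over the list alone. Krt16 rose by 4.05 ± 0.55 and Sprr2d by 6.54 ± 0.75, and the list's median difference was 3.92, or 3.55 with genes below background at their bound. The stress keratin list had adjusted p = 9.99e-26, and adjusted p = 0.0779 with an estimated correlation. Of 17 antimicrobial and alarmin genes, 8 rose and 0 fell, 9 and 0 adjusted over the list alone. The antimicrobial list had adjusted p = 1.11e-10, and adjusted p = 0.0967 with an estimated correlation. Il33, an epithelial alarmin cytokine, rose by 2.01 ± 0.49. Of 29 cell cycle genes, 12 rose, among them Mcm6 by 0.71 ± 0.13 and Birc5 by 1.53 ± 0.30, and 19 rose when adjusted over the list alone. The cell cycle list had adjusted p = 1.56e-10, and adjusted p = 0.22 with an estimated correlation.

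The neutrophil, IL-17 axis, general inflammatory cytokine and T cell lists were higher in back skin. Of 14 neutrophil genes, 10 rose and 1 fell, 10 and 2 adjusted over the list alone, with Stfa3 up by 5.67 ± 0.70 and Stfa2 by 5.18 ± 0.77. The neutrophil list had adjusted p = 1.15e-06, and adjusted p = 0.231 with an estimated correlation. Of 23 genes of the IL-17 and IL-23 axis, 9 rose and 1 fell, 13 and 1 adjusted over the list alone, with Il1f8, an IL-36 cytokine, up by 2.86 ± 0.35. The IL-17 list had adjusted p = 7.76e-07, and adjusted p = 0.297 with an estimated correlation. Il17a itself was below background in both back skin groups. Of 25 general inflammatory cytokine genes, 7 rose and 0 fell, 11 and 0 adjusted over the list alone, with the chemokine Ccl3, above background on 1 of 8 sham arrays, up by 5.48 ± 0.92 (4.64 with values under background raised to it) and Il18 by 1.52 ± 0.21. The cytokine list had adjusted p = 5.33e-06, and adjusted p = 0.347 with an estimated correlation. Of 19 T cell genes, 6 rose and 1 fell, 7 and 1 adjusted over the list alone, with the costimulatory receptor Icos up by 2.75 ± 0.48. The T cell list had adjusted p = 0.00158, and adjusted p = 0.364 with an estimated correlation.

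The sebaceous, adipocyte and dendritic cell lists were lower in back skin. Of 26 sebaceous and sebum lipid genes, 17 fell and 1 rose, 20 and 1 adjusted over the list alone, with Dgat2l6, an acyltransferase gene, down from 10.83 ± 0.75 to 6.99 ± 1.17. The sebaceous list had adjusted p = 5.17e-17, and adjusted p = 0.0779 with an estimated correlation. Of 13 adipocyte genes, 9 fell and 0 rose, 10 and 0 adjusted over the list alone, among them Pck1, an enzyme of gluconeogenesis and glyceroneogenesis, which fell by 2.85 ± 0.31. The adipocyte list had adjusted p = 3.42e-10, and adjusted p = 0.0779 with an estimated correlation. Of 15 dendritic and Langerhans cell genes, 9 fell and 0 rose, 11 and 1 adjusted over the list alone, among them the MHC class II gene H2-Eb1, which fell by 1.73 ± 0.24, and the lectin gene Cd209a, which fell by 2.53 ± 0.34. The dendritic cell list had adjusted p = 1.57e-07, and adjusted p = 0.0807 with an estimated correlation.

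The type 2 list did not pass in back skin (adjusted p = 0.0601), with 8 genes up and 3 down of 26, 10 and 5 adjusted over the list alone. Il4, Il13 and Il31, cytokines of type 2 immunity and itch, were below background in all 4 groups, and Tslp differed by -0.04 ± 0.42 (adjusted p = 0.961). Chil3 and Arg1, products of alternatively activated macrophages, rose by 3.66 ± 0.57 and 4.04 ± 0.75, with Chil3 above background on 1 of 8 sham arrays and its difference 3.14 with values under background raised to it. Ccl22, a ligand of the chemokine receptor CCR4, fell by 2.42 ± 0.47, and Ccl17, which binds the same receptor, differed by -0.82 ± 0.35 (adjusted p = 0.116), or by -0.35 with values under background raised to it, with 2 of 8 HDM arrays above background. Of 38 cornified envelope genes 13 rose and 9 fell, 14 and 10 adjusted over the list alone (adjusted p = 0.195), with the peptidase gene Klk7 up by 1.68 ± 0.16 and Rptn, which encodes repetin, up by 3.85 ± 0.55. In that list the median was 0.11 and the mean -0.09. Of 25 ceramide and lipid barrier genes 4 rose and 5 fell, as many as adjusted over the list alone (adjusted p = 0.785), where the ceramide synthase gene Cers4 fell by 4.09 ± 0.45 and the fatty acid hydroxylase gene Fa2h fell from 16.67 ± 0.70 to 11.33 ± 1.71. Further lists that did not pass in back skin were cholesterol synthesis (adjusted p = 0.785), JAK-STAT genes (0.294), clock genes (0.882), Hox genes (0.349), B and plasma cells (0.739) and eosinophils (0.614). Those of mast cells (0.0829), basophils (0.785), macrophages (0.117), natural killer cells (0.195), endothelial cells (0.294), cartilage (0.662), Schwann cells (0.065), melanocytes (0.931) and erythroid cells (0.617) did not pass either. Below background in both back skin groups were 6 of 7 eosinophil, 7 of 12 B and plasma cell, 10 of 16 cartilage and 16 of 33 Hox genes. These lists could therefore hardly show a change. The matrix-degrading enzyme genes Mmp13 and Mmp3 rose by 5.23 ± 0.58 and 5.54 ± 0.68 while the matrix list as a whole did not pass (adjusted p = 0.408). Klk8, a peptidase gene on the itch list, rose by 4.43 ± 0.45 (adjusted p = 0.0601 for the list).

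Hair follicle and skeletal muscle genes varied between sham back arrays. The mean of the hair list was 12.79 ± 3.03 in sham and 13.12 ± 0.71 in HDM back skin, that of the muscle list 12.44 ± 1.78 and 12.15 ± 0.45, and 0 genes of either list passed (adjusted p = 0.425 and 0.42). The interferon list had 1 gene down and 0 up of 28 (adjusted p = 0.5). That gene, Iigp1, an interferon-induced GTPase gene, differed by -1.22 ± 0.34 with all mice and by -0.98 (adjusted p = 0.0667) without sham mice 1 and 2.

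In all, 1372 rows were higher and 1901 lower in HDM than in sham back skin, 14.7% of those tested, and 456 and 766 of them differed by at least 1 on the log2 scale. Without sham mice 1 and 2 the counts were 1340 and 1758, 2508 of the 3273 calls were shared and 0 were opposite, and 18 lists passed in place of 10, among them the hair list with a median of -0.93 (adjusted p = 1.58e-05) and the muscle list (adjusted p = 0.00103), both lower. The other 6 lists that passed only then were higher, namely type 2 (adjusted p = 0.00388, median 0.31), itch (0.00388), cornified envelope (0.00445), ceramide (0.0159), macrophage (0.00244) and endothelial genes (0.0438). Among lists called either way, the median then went from -0.74 to -0.50 for dendritic cells, from 0.60 (0.47 with genes below background at their bound) to 0.98 for the IL-17 axis and from 0.34 (0.31 so bounded) to 0.58 for T cells. For general inflammatory cytokines it went from 0.76 to 1.49, with 13 genes up in place of 7. The share of called rows that were higher was 41.9%, and 63.6% with array medians made equal, when 2433 rows were higher and the median of all rows moved from 0.01 to 0.13. With the means of the muscle and adipocyte lists as covariates, 89 rows were higher and 36 lower.

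HDM against sham in ear asks the same of the ear. S100a9, S100a8 and Defb3 were among the 6 largest named rises at both sites. S100a9 and S100a8 rose by 12.03 ± 0.84 and 11.81 ± 0.79 (adjusted p = 4.80e-12 and 1.25e-12), and Defb3 by 11.86 ± 0.69 as measured (adjusted p = 5.84e-14). Only 2 of 8 sham ear arrays were above background for Defb3, and with values under background raised to it the difference was 10.99. The stress keratin gene Krt16 rose by 10.37 ± 0.55 (adjusted p = 6.50e-15). Cstdc5, of the cystatin family of protease inhibitors, rose by 10.93 ± 0.78. The difference between sites passed for S100a8 and Defb3 but not for S100a9 (adjusted p = 0.0603). The genes named for the largest falls were epidermal, muscle and hair genes. Flg2, a filaggrin-like barrier protein gene, fell by 6.79 ± 1.18 (adjusted p = 3.50e-05), with 18.35 ± 0.18 in sham and 11.56 ± 4.93 in HDM ears, Myh4, a fast myosin heavy chain gene, fell by 5.17 ± 0.62 (adjusted p = 1.73e-07), and Pvalb, a calcium-binding protein gene of fast muscle, fell by 4.38 ± 0.64. Krt77 fell by 4.81 ± 0.78 (adjusted p = 1.37e-05). The hair keratin-associated genes Krtap3-2 and Krtap3-3, whose rows hold identical values, fell by 3.96 ± 0.75. For each of these genes all 8 HDM arrays lay on that side of the sham mean.

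Of 26 stress keratin and small proline-rich protein genes 24 rose and 0 fell in ear, as many as adjusted over the list alone, with Sprr2d up by 10.49 ± 0.75 and Sprr2b, above background on 2 of 8 sham arrays, by 8.78 ± 0.62 (8.24 with values under background raised to it). The list's median difference was 5.53, or 4.45 with genes below background at their bound. The stress keratin list had adjusted p = 2.97e-25, and adjusted p = 0.0779 with an estimated correlation. Of 17 antimicrobial and alarmin genes 12 rose and 0 fell, as many as adjusted over the list alone. The antimicrobial list had adjusted p = 1.87e-11, and adjusted p = 0.0807 with an estimated correlation. Of 29 cell cycle genes 28 rose and 0 fell, as many as adjusted over the list alone, with the replication helicase gene Mcm6 up by 1.37 ± 0.13. The cell cycle list had adjusted p = 5.22e-21, and adjusted p = 0.0807 with an estimated correlation.

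**Figure D2:**
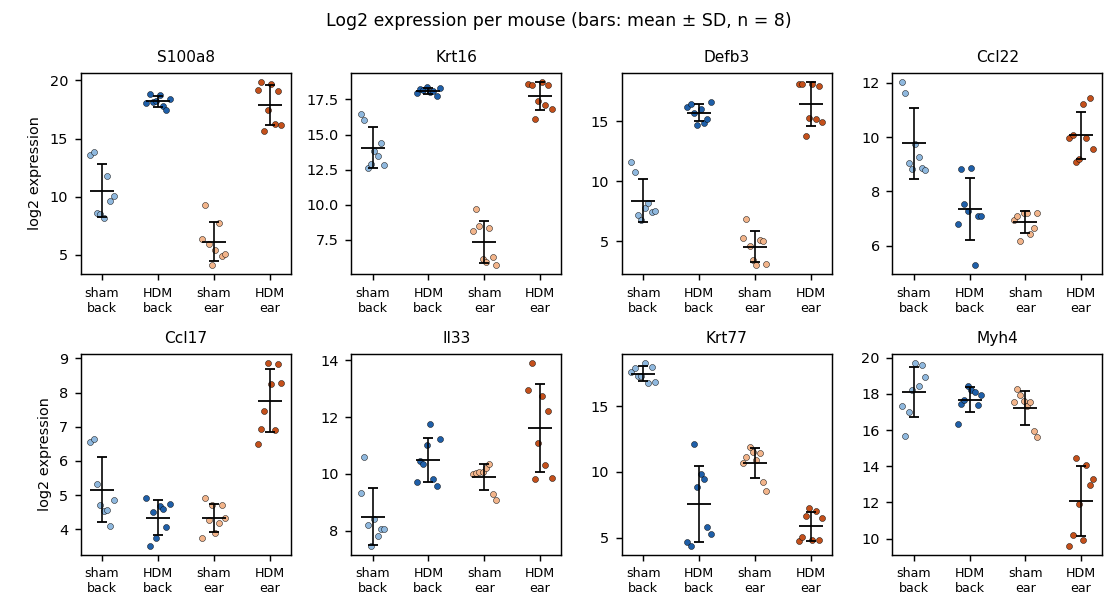
Log2 expression of 8 named genes in every mouse, with points for mice and bars for the mean ± SD (n = 8 per group). S100a8 reaches 18.20 ± 0.46 in HDM back skin and 17.91 ± 1.73 in HDM ear, from 10.51 ± 2.28 and 6.11 ± 1.68 in sham.

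Macrophage and neutrophil genes rose in ear. Of 17 macrophage and monocyte genes 17 rose, as many as adjusted over the list alone, with the Fc receptor gene Fcgr3 up by 3.96 ± 0.39 and the scavenger receptor gene Cd163 by 3.39 ± 0.36. The macrophage list had adjusted p = 1.07e-14, and adjusted p = 0.0807 with an estimated correlation. Of 14 neutrophil genes 11 rose and 1 fell, 12 and 1 adjusted over the list alone, with Stfa3, above background on 3 of 8 sham arrays, up by 9.28 ± 0.70 (8.84 with values under background raised to it) and Stfa2 at least 340-fold higher. The neutrophil list had adjusted p = 1.42e-09, and adjusted p = 0.115 with an estimated correlation. Of 19 T cell genes 13 rose and 0 fell, 13 and 1 adjusted over the list alone, with Icos up by 4.18 ± 0.48, a median of 1.17 and one of 0.36 with genes below background at their bound. The T cell list had adjusted p = 0.000149, and adjusted p = 0.325 with an estimated correlation. Of 14 mast cell genes 6 rose and 0 fell, as many as adjusted over the list alone, with the tryptase gene Tpsab1, above background on 1 of 8 sham arrays, up by 3.09 ± 0.37 (2.70 with values under background raised to it). The mast cell list had adjusted p = 0.0148, and adjusted p = 0.347 with an estimated correlation. Of 14 endothelial genes 6 rose and 2 fell, 7 and 2 adjusted over the list alone, with the adhesion molecule Selp up by 2.93 ± 0.36 and the lymphatic marker Lyve1 by 1.99 ± 0.28. The endothelial list had adjusted p = 0.0235, and adjusted p = 0.364 with an estimated correlation. The T cell, mast cell and endothelial lists did not pass once dim rows were left out (adjusted p = 0.0673, 0.126 and 0.128).

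The general inflammatory cytokine, IL-17 axis, type 2, interferon and JAK-STAT lists were higher in ear. Of 25 general inflammatory cytokine genes 23 rose and 0 fell, 23 and 1 adjusted over the list alone, with the monocyte chemokines Ccl2 up by 4.48 ± 0.49 and Ccl12 at least 25.7-fold higher. The cytokine list had adjusted p = 1.24e-13, and adjusted p = 0.111 with an estimated correlation. Of 23 genes of the IL-17 and IL-23 axis 20 rose and 0 fell, 21 and 0 adjusted over the list alone, with Il1f6, an IL-36 cytokine, up by 6.09 ± 0.60 and Il19 at least 22.7-fold higher. The IL-17 list had adjusted p = 4.12e-12, and adjusted p = 0.111 with an estimated correlation. Of 26 type 2 genes 14 rose and 0 fell, 16 and 0 adjusted over the list alone, with the chemokine Ccl8 up by 5.96 ± 0.54, Ccl22 up by 3.20 ± 0.47 and Ccl17 at least 5.88-fold higher. The type 2 list had adjusted p = 1.00e-07, and adjusted p = 0.0779 with an estimated correlation. Of 28 interferon response genes 20 rose and 0 fell, 21 and 0 adjusted over the list alone, with Cxcl9, an interferon-induced chemokine above background on 2 of 8 sham arrays, up by 3.83 ± 0.48 (3.47 with values under background raised to it) and Cxcl10 at least 2.54-fold higher. The median of that list was 0.97, or 0.51 with genes below background at their bound. The interferon list had adjusted p = 1.01e-07, and adjusted p = 0.279 with an estimated correlation. Of 17 JAK-STAT genes 7 rose and 2 fell, 8 and 2 adjusted over the list alone, with the IL-4 receptor gene Il4ra up by 3.98 ± 0.40 and Stat3 by 1.65 ± 0.22. The JAK-STAT list had adjusted p = 0.00158, and adjusted p = 0.325 with an estimated correlation. The JAK-STAT call was lost once dim rows were left out (adjusted p = 0.0883).

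Single cytokines gave a mixed picture in ear. Il33 rose by 1.72 ± 0.49 (adjusted p = 0.006). With the negative control median, which itself differed between sham and HDM ear, as a covariate it rose by 1.30 and did not pass (adjusted p = 0.167). In HDM mice 3, 6 and 8 it was 9.83, 10.32 and 9.84, inside the sham ear range of 9.07 to 10.35. HDM mice 1, 2, 4, 5 and 7 lay between 11.07 and 13.9. Il17a was below background on all sham ear arrays, and its mean in HDM ears, 4.27 ± 1.61, was also below the negative control median there, 4.82 ± 0.14. It passed (adjusted p = 0.03), and its call was lost without HDM ear mouse 1 (adjusted p = 0.0796), 2 (0.0935) or 5 (0.0956), or without sham ear mouse 7 (0.0523). Tslp differed by -0.33 ± 0.42 (adjusted p = 0.616) and Ifng, below background on all sham ear arrays, did not pass (adjusted p = 0.79). Of 25 itch genes 9 rose and 3 fell, 10 and 3 adjusted over the list alone (adjusted p = 0.0615), with Osmr, a subunit of the oncostatin M and IL-31 receptors, up by 1.75 ± 0.24.

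**Figure D3:**
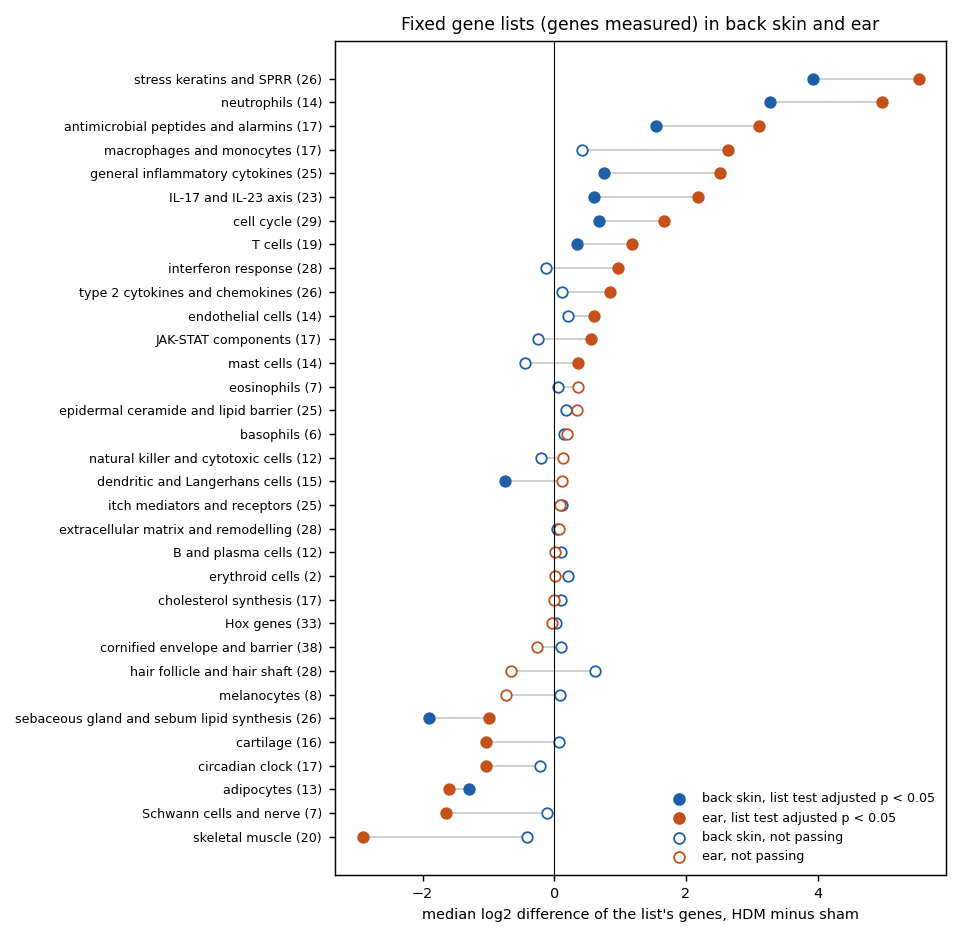
Median log2 difference, HDM minus sham, of the measured genes of each of the 33 lists in back skin (blue) and ear (orange), with filled points where the list test passed at the preset correlation and open points where it did not. The stress keratin list has a median of 3.92 in back skin and 5.53 in ear, and the neutrophil list 3.28 and 4.98. With genes below background at their bound they are 3.55 and 4.45 for stress keratins and 3.16 and 4.89 for neutrophils, so the order in ear is the opposite.

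The muscle, cartilage, adipocyte, Schwann cell, sebaceous and clock lists were lower in ear. All 20 skeletal muscle genes fell, as many as adjusted over the list alone, among them the calcium pump gene Atp2a1, which fell by 3.86 ± 0.55, and the list's mean went from 11.98 ± 0.75 to 8.98 ± 0.90. The muscle list had adjusted p = 8.41e-13, and adjusted p = 0.22 with an estimated correlation. Of 16 cartilage genes 12 fell and 0 rose, 13 and 0 adjusted over the list alone, and Chad, which encodes chondroadherin, fell by 2.74 ± 0.38. The cartilage list had adjusted p = 3.72e-07, and adjusted p = 0.0807 with an estimated correlation. Of 13 adipocyte genes 12 fell and 0 rose, as many as adjusted over the list alone, and the lipid droplet gene Plin1 fell by 2.27 ± 0.25. The adipocyte list had adjusted p = 1.24e-08, and adjusted p = 0.0793 with an estimated correlation. Of 7 Schwann cell genes 4 fell and 0 rose, as many as adjusted over the list alone, and the cadherin gene Cdh19 fell by 2.04 ± 0.38. The Schwann cell list had adjusted p = 0.00705, and adjusted p = 0.212 with an estimated correlation. Of 26 sebaceous genes 12 fell and 1 rose, 15 and 1 adjusted over the list alone, and the melanocortin receptor gene Mc5r fell by 1.99 ± 0.35. The sebaceous list had adjusted p = 0.000462, and adjusted p = 0.383 with an estimated correlation. Of 17 clock genes 10 fell and 4 rose, 11 and 4 adjusted over the list alone, and the core activators Arntl and Npas2 fell by 1.42 ± 0.18 and 1.88 ± 0.32. The clock list had adjusted p = 0.0499, and adjusted p = 0.509 with an estimated correlation. The clock call was lost with dim rows left out (adjusted p = 0.119), with array weights (adjusted p = 0.0649) and with the hair list as a covariate (adjusted p = 0.0602).

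The cornified envelope list went both ways in ear, with 11 genes up and 14 down of 38, 11 and 15 adjusted over the list alone (adjusted p = 0.801), a median of -0.27 and a mean of 0.02, while Lce1m, a late cornified envelope gene, fell by 3.46 ± 0.40. The ceramide list had 12 genes up and 4 down of 25, 12 and 5 adjusted over the list alone (adjusted p = 0.0709), with Sptlc2, a subunit of the enzyme that starts sphingolipid synthesis, up by 1.67 ± 0.22. The matrix list had 12 up and 7 down of 28, as many as adjusted over the list alone (adjusted p = 0.0601), with tenascin C (Tnc) up by 4.01 ± 0.48 and the protease inhibitor Timp1 at least 33.3-fold higher. Lists that did not pass in ear also included cholesterol synthesis (adjusted p = 0.773), Hox genes (0.593), B and plasma cells (0.981), eosinophils (0.511), basophils (0.114), dendritic and Langerhans cells (0.497), natural killer and cytotoxic cells (0.456), hair (0.107), melanocytes (0.176) and erythroid cells (0.981, with 2 genes measured). Below background in both ear groups were 5 of 7 eosinophil, 9 of 12 B and plasma cell, 8 of 12 natural killer cell and 25 of 33 Hox genes. These lists could therefore hardly show a change.

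In all, 3638 rows were higher and 3438 lower in HDM than in sham ear, 31.9% of those tested, and 1675 and 1396 of them differed by at least 1 on the log2 scale. The share higher was 51.4%, and 46.6% with quantile normalization, with 3369 rows higher and 3860 lower. The negative control median fell from 5.20 ± 0.10 in sham to 4.82 ± 0.14 in HDM ear. Without sham back mice 1 and 2, which enter the ear test only through the pooled spread, the clock list did not pass (adjusted p = 0.0505), and the ceramide (0.041), matrix (0.0459), itch (0.0415) and hair (0.00938) lists did. With the negative control median as a covariate, an alternative chosen after seeing the data, 2051 rows were higher and 1578 lower. That median was 5.09 to 5.38 on sham and 4.61 to 4.98 on HDM ear arrays, without overlap. Adjusting for it may therefore also remove HDM effect. With the means of the muscle and adipocyte lists, which fell with HDM in ear, as covariates, 62 rows were higher and 1 lower.

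The HDM effects at both sites and their difference address whether ear and back skin responded alike. Across the rows tested, the differences had a Pearson correlation of 0.63 and a Spearman correlation of 0.47, across genes, which are not independent replicates. Of the rows called, 866 were higher at both sites, against 225 if the calls were independent, and 973 were lower at both, against 294. For 33 rows the call was higher in back skin and lower in ear, and for 76 the reverse.

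The difference between the effects passed for 2251 rows, and the macrophage and muscle lists differed most among lists. Alox8, an arachidonate lipoxygenase gene, went from 7.07 ± 1.68 to 15.72 ± 0.65 in ear and from 12.16 ± 1.88 to 11.49 ± 1.10 in back skin, a difference between effects of 9.32 ± 0.94 (adjusted p = 1.87e-07). Ccl22 fell in back skin and rose in ear, with a difference of 5.63 ± 0.66 (adjusted p = 2.10e-06). The difference also passed for Ccl17 (adjusted p = 2.10e-06), with no size given since its sham ear level was below background. Cd209e, a C-type lectin gene, differed by 5.65 ± 0.58, and Krt16, with a lower sham level in ear, by 6.32 ± 0.78. Krt77 and Cyp2g1, which fell further in back skin, differed by 5.12 and 6.43. The myosin gene Myh4 differed by -4.75 ± 0.88. The test also passed for Klk14 (adjusted p = 0.000511), below background in sham ear, and for the embryonic myosin gene Myh3 (adjusted p = 0.000103), below background in both back skin groups, so neither size is given.

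Of 17 macrophage genes the effect was more positive in ear for 14, and for 15 adjusted over the list alone, with a median difference of 2.26. The macrophage list had adjusted p = 1.11e-14, and adjusted p = 0.0807 with an estimated correlation. It was more positive for 13 of 28 interferon genes, 16 adjusted over the list alone, with Cxcl9 at 4.40, or 4.04 with values under background raised to it (adjusted p = 4.37e-10, and adjusted p = 0.2 with an estimated correlation), and for 12 of 29 cell cycle genes, 17 adjusted over the list alone. The cell cycle list had adjusted p = 1.11e-10, and adjusted p = 0.22 with an estimated correlation. The same held for 7 of 15 dendritic and Langerhans cell genes, 9 adjusted over the list alone, with H2-Eb1 at 1.84 (adjusted p = 1.01e-07, and adjusted p = 0.0807 with an estimated correlation), and for 9 of 17 JAK-STAT genes, 11 adjusted over the list alone, with Il4ra at 2.44. The JAK-STAT list had adjusted p = 1.85e-06, and adjusted p = 0.112 with an estimated correlation. General inflammatory cytokines had 11 of 25 genes more positive and 1 more negative, 16 and 1 adjusted over the list alone, with Ccl2 at 3.72 and Il18 at -1.98. The cytokine list had adjusted p = 6.22e-07, and adjusted p = 0.325 with an estimated correlation. Type 2 genes had 10 of 26 more positive and 1 more negative, 12 and 1 adjusted over the list alone. The type 2 list had adjusted p = 1.43e-05, and adjusted p = 0.106 with an estimated correlation.

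Of 20 muscle genes the effect was more negative in ear for 12, and for 20 adjusted over the list alone, with a median of -2.62. The muscle list had adjusted p = 1.24e-13, and adjusted p = 0.209 with an estimated correlation. Of 16 cartilage genes, 10 of which were below background in both back skin groups, it was more negative for 9, and for 11 adjusted over the list alone. The cartilage list had adjusted p = 1.51e-09, and adjusted p = 0.0779 with an estimated correlation. Of 26 sebaceous genes it was more positive in ear for 10 and more negative for 1, 12 and 2 adjusted over the list alone, with Dgat2l6 at 4.12. The sebaceous list had adjusted p = 7.81e-05, and adjusted p = 0.347 with an estimated correlation. Of 14 mast cell genes it was more positive for 4, and for 12 adjusted over the list alone, with the mast cell protease gene Mcpt4 at 1.94. The mast cell list had adjusted p = 7.01e-06, and adjusted p = 0.0967 with an estimated correlation. Of 14 neutrophil genes it was more positive for 4, and for 5 adjusted over the list alone. The neutrophil list had adjusted p = 0.00017, and adjusted p = 0.347 with an estimated correlation.

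The IL-17 axis, antimicrobial, stress keratin, hair, ceramide, natural killer cell and clock lists passed as well. IL-17 axis genes (5 of 23 more positive in ear, 8 adjusted over the list alone) had adjusted p = 7.43e-05, and adjusted p = 0.355 with an estimated correlation. Antimicrobial genes (6 of 17, 8 adjusted over the list alone) had adjusted p = 0.00141, and adjusted p = 0.383 with an estimated correlation. Stress keratin genes (9 of 26, 12 adjusted over the list alone) had adjusted p = 8.25e-07, and adjusted p = 0.347 with an estimated correlation. Their mean was 10.98 ± 1.82 in HDM ear and 11.25 ± 0.31 in HDM back skin, from 5.55 ± 0.23 and 7.77 ± 0.66 in sham. For cell cycle genes it was 9.75 ± 0.56 and 9.91 ± 0.24, from 8.08 ± 0.23 and 9.20 ± 0.43. In these lists the more positive effect in ear thus went with a lower sham level there, not with a higher HDM level. The hair list passed with 0 of 28 genes called, at adjusted p = 0.0148, and adjusted p = 0.744 with an estimated correlation. Ceramide genes (adjusted p = 0.0499, and adjusted p = 0.566 with an estimated correlation), natural killer cell genes (adjusted p = 0.0446, and adjusted p = 0.325 with an estimated correlation) and clock genes (adjusted p = 0.0438, and adjusted p = 0.49 with an estimated correlation) lay near the threshold. Without sham back mice 1 and 2 the hair list turned to a median of 0.44 (adjusted p = 0.463), and the ceramide (0.872) and natural killer cell (0.066) calls were lost. The effect was then more positive in ear for 1 of 14 neutrophil genes, 7 of 28 interferon genes and 7 of 25 general inflammatory cytokine genes, in place of 4, 13 and 11. The median went from 1.04 to 0.62 for antimicrobial genes and from 1.02 to 0.59 for mast cells. The cornified envelope list (adjusted p = 0.799) had a median of -0.25 and a mean of 0.11.

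Of these 2251 rows, 1503 had the more positive effect in ear, 66.8%, and 1497 differed by at least 1. Of the rows with a call in a single site, 999 were higher and 540 lower in ear alone, and 118 were higher and 266 lower in back skin alone. The share with the more positive effect in ear was 50.3% with quantile normalization and 45.8% with array medians made equal, when the median of all rows moved from -0.01 to -0.13. The count was 453 with the muscle and adipocyte lists as covariates and 452 with the negative control median, and without sham back mice 1 and 2 it was 1885, 1660 of them shared.

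**Figure D4:**
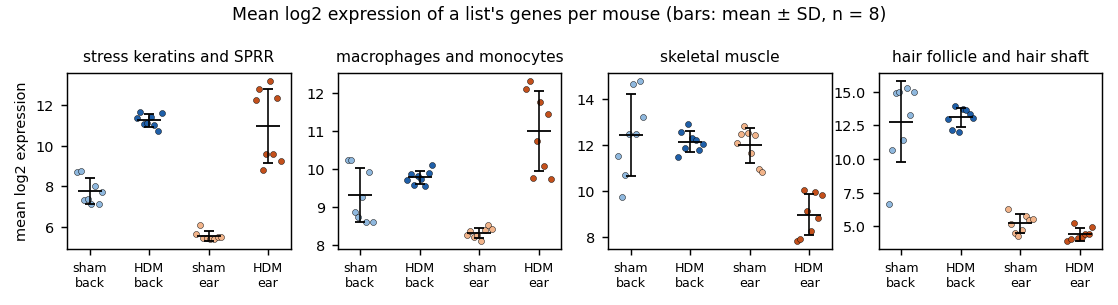
Mean log2 expression of the genes of 4 lists in every mouse, with points for mice and bars for the mean ± SD (n = 8 per group). The muscle mean is 11.98 ± 0.75 in sham ear and 8.98 ± 0.90 in HDM ear, and the hair mean of sham back mice spans 6.69 to 15.27.

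Sham ear against sham back skin gives the difference between the sites without HDM. The cartilage list was higher in ear and the hair list higher in back skin. The keratin gene Krt2 was higher in ear (adjusted p = 1.53e-23). Its mean was 4.33 ± 0.76 in back skin, where 2 of 8 arrays were above background, and 19.82 ± 0.18 in ear, close to the upper limit of the values, so no size is given. Cytl1, a cytokine-like gene of cartilage, was higher by 12.97 ± 0.37 (adjusted p = 1.53e-23), or by 12.51 with values under background raised to it, since 3 of 8 sham back arrays were above it, and Chad at least 117-fold. Mup19 was at least 2040-fold lower in ear and Mup22 at least 1809-fold lower, genes whose family shares much sequence. The hair keratin gene Krt27 differed by -10.58 ± 0.77 (adjusted p = 1.74e-12) and Tchh, which encodes trichohyalin of the inner root sheath, by -9.47 ± 0.65.

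All 28 hair genes were lower in ear, as many as adjusted over the list alone, with a median of -8.32, or -7.88 with genes below background at their bound. The hair list had adjusted p = 8.78e-32, and adjusted p = 0.0621 with an estimated correlation. Of 16 cartilage genes 14 were higher and 1 lower, as many as adjusted over the list alone (adjusted p = 4.53e-19), of 13 adipocyte genes 11 were lower, as many as adjusted over the list alone (adjusted p = 1.36e-13), and of 33 Hox genes 15 were lower and 2 higher, as many as adjusted over the list alone (adjusted p = 5.10e-05). Hoxc8, a gene of trunk identity, was at least 11.5-fold lower in ear and Hoxc6 at least 5.54-fold. These 3 lists also passed with an estimated correlation (adjusted p = 0.00148, 0.00869 and 0.00869). Of 17 clock genes 13 were higher and 1 lower, 14 and 1 adjusted over the list alone, with the output regulator Dbp at 4.11 ± 0.40 and the repressor Cry2 at 2.84 ± 0.27. The clock list had adjusted p = 7.33e-08, and adjusted p = 0.0621 with an estimated correlation. Of 29 cell cycle genes 22 were lower, and 24 adjusted over the list alone. The cell cycle list had adjusted p = 3.79e-12, and adjusted p = 0.237 with an estimated correlation. Of 17 cholesterol synthesis genes 12 were higher and 1 lower, 13 and 1 adjusted over the list alone, with lanosterol synthase (Lss) at 2.58 ± 0.23. The cholesterol list had adjusted p = 2.83e-06, and adjusted p = 0.363 with an estimated correlation.

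The stress keratin, interferon and macrophage lists had lower levels in sham ear. Of 26 stress keratin genes 12 were lower, and 15 adjusted over the list alone, with Krt16 at -6.72 ± 0.55. The stress keratin list had adjusted p = 1.03e-07, and adjusted p = 0.417 with an estimated correlation. Of 28 interferon genes 14 were lower, as many as adjusted over the list alone (adjusted p = 9.81e-06, and adjusted p = 0.417 with an estimated correlation), and of 17 macrophage genes 7, as many as adjusted over the list alone. The macrophage list had adjusted p = 0.000451, and adjusted p = 0.516 with an estimated correlation. Lower in ear as lists were also dendritic cell genes (6 of 15 lower, adjusted p = 0.00555, and adjusted p = 0.417 with an estimated correlation) and general inflammatory cytokines (adjusted p = 0.0282, and adjusted p = 0.669 with an estimated correlation). So were antimicrobial genes (adjusted p = 0.037, and adjusted p = 0.634 with an estimated correlation) and IL-17 axis genes (adjusted p = 0.0476, and adjusted p = 0.67 with an estimated correlation). Higher were ceramide genes (11 of 25, adjusted p = 0.0284, and adjusted p = 0.602 with an estimated correlation) and Schwann cell genes (4 of 7, adjusted p = 0.0364, and adjusted p = 0.417 with an estimated correlation). Without sham back mice 1 and 2 the calls for dendritic cells (adjusted p = 0.195), general inflammatory cytokines (0.273), antimicrobial genes (0.134), IL-17 axis genes (0.346, with the median at 0.02) and Schwann cells (0.0818) were lost. The matrix (0.0451) and muscle (0.00375) lists then passed. The median went from -1.70 (-1.49 with genes below background at their bound) to -0.97 for stress keratins and from -0.84 (-0.75 so bounded) to -0.47 for macrophages, 9 interferon genes were lower in place of 14, and these 3 lists still passed. The cornified envelope list, with 18 genes higher and 14 lower of 38, did not pass (adjusted p = 0.58), nor did the muscle list (adjusted p = 0.193) or the type 2 list (adjusted p = 0.104), with a median of 0.03 (0 with genes below background at their bound) and a mean of -0.61. S100a7a, an alarmin gene, was at least 16.8-fold lower in ear and Lcn2, an antimicrobial iron-binding protein gene, differed by -4.24 ± 0.74. In all, 3469 rows were higher and 3124 lower in sham ear, and 1187 and 1520 of them differed by at least 1. The share higher was 52.6%, and 67.3% with array medians made equal, when the median of all rows moved from 0.04 to 0.16. With the mean of the hair list as a covariate 838 rows were higher and 1378 lower, and with the negative control median 1355 and 1346. Without sham back mice 1 and 2 the counts were 3352 and 2955, and 5724 of the 6593 calls were shared.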

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

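The test of hair growth stage in sham back mice 1 and 2, the test of a shift shared by all rows of an array and the comparison of their control statistics with back skin arrays alone were chosen only after the results were seen, and the other tests below were written down first. The exception is the muscle difference among genes well above background, which was not written down first.

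Of 260 groups of 8 values (control statistics, list means and named genes), 13 had a mouse far from the other 7, and chance gives about 1 in 20 such groups. The ratio of the gap to the whole range was 0.673 for the spread of the negative controls in sham back mouse 1 and 0.605 for the positive control median in HDM back mouse 4. In sham ear it was 0.592 for the interferon list (mouse 4), 0.653 for the stress keratin list and 0.527 for the cell cycle list (both mouse 2), and in HDM back skin 0.528 for the erythroid list (mouse 8). Among genes it was 0.618 for Klk14 in sham ear (mouse 2), 0.629 for Tslp (mouse 5), 0.537 for Il17a (mouse 8) and 0.564 for Pvalb (mouse 1) in HDM back skin. For Ifng it was 0.697 in sham back skin (mouse 1), 0.593 in sham ear (mouse 4) and 0.54 in HDM ear (mouse 5), with values near or below background. A count of 13 in 260 is what chance alone gives.

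The HDM effect differed between ear and back skin for 2251 rows. Of 100 draws of the agent labels within each tissue, 1, the real one, reached that count, and the highest other was 3. Such draws also break up the HDM effect that both sites share and move it into the spread. They therefore cannot decide whether the effects differ between sites. For 19 lists the difference passed at the preset correlation, and 0 of the 19 held with an estimated correlation. They had median values (ear minus back) of 2.26 for macrophages, 1.77 for neutrophils, 1.70 for stress keratins, 1.63 for general inflammatory cytokines, 1.22 for sebaceous genes, 1.06 for dendritic cells and 1.05 for JAK-STAT genes. They were 1.04 for antimicrobial genes (0.62 without sham back mice 1 and 2), 1.02 for interferon genes, 1.02 for mast cells (0.59 without them), 1.01 for the IL-17 axis, 0.99 for the cell cycle, 0.83 for type 2 genes, 0.38 for natural killer cells and 0.29 for ceramide genes (0.072 without them). They were negative for muscle (-2.62), hair (-1.30, but 0.44 without these mice), cartilage (-1.20) and clock genes (-0.58), and genes below background in a group enter all these medians as measured.

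Among named genes, the difference between effects was positive for Alox8 (9.32), Cyp2g1 (6.43), Krt16 (6.32), Cstdc5 (5.81), Cd209e (5.65), Ccl22 (5.63), Krt77 (5.12), Serpinb6d (4.57), Defb3 (4.56), Serpina3j (4.41), Ccl17 (4.24), S100a8 (4.12), Sprr2d (3.95), Serpina3b (3.55) and Fa2h (3.37). It was negative for Klk14 (-4.88), Myh4 (-4.75), Krtap3-2 and Krtap3-3 (-4.04 each, from identical values), Myh3 (-4.01) and Pvalb (-3.30). Without sham back mice 1 and 2 the value for Krtap3-2 and Krtap3-3 was -2.67 (adjusted p = 0.00556). Their HDM effect in back skin was then -1.28 (adjusted p = 0.0499), in place of 0.085. Klk14 and Ccl17 lay below background in sham ear, Serpina3j in HDM back skin and Myh3 in both back skin groups, and Defb3 on 6 of 8 sham ear arrays, so these sizes are not valid as measured and for Klk14 and Myh3 the direction is open as well.

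A signal also appeared in rows outside the comparisons. Of 5222 negative control rows, 491 were lower and 21 higher in HDM than in sham ear. Their median per array was 5.20 ± 0.10 in sham and 4.82 ± 0.14 in HDM ear (n = 8 mice each). Between sham ear and sham back skin, at 4.72 ± 0.19, 735 were higher and 28 lower, so sham ear stands apart and the comparison of sites is touched as well.

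The arrays of sham back mice 1 and 2 stood apart, with higher antimicrobial and lower hair genes than the other 6. Of 6 control statistics of these arrays, 0 lay outside the range of the 30 others, but that range spans 2 tissues with different control levels. Against the 14 other back skin arrays 1 of 6 lay outside and against the 6 other sham back arrays 3, with mouse 1 at the lowest correlation with its group (0.975), so array quality stays open. On the genes that part the other sham from HDM back arrays, with sham at 0 and HDM at 1, they lay at 0.334 and 0.257 and the lowest HDM array at 0.868, which argues against HDM samples with a sham label. Another stage of hair growth stays open, since the antimicrobial list means of 9.25 and 9.44, higher than on all 6 others, are part of how these arrays were seen to differ, and a state of the skin was not tested.

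The HDM ear arrays spread widely in epidermal and inflammatory genes. Of these 8 arrays, 4 had a control statistic outside the range of the 24 others. They were mice 1, 2, 5 and 8, with positive control medians of 10.27 to 10.3 against at most 10.26 on the others. Mouse 8 had a low score on the second component (9.58), and mouse 7, with a high one (99.3), lay inside the range. A comparison with other groups cannot tell what makes these 8 arrays differ from each other, so array quality stays open. The range of the muscle list mean over the arrays was 2.19 and that of the cartilage list 1.39, against 3.24 for the antimicrobial list, so that unequal content of the punch cannot be told apart from a range of severity, because the muscle range lies between the bounds set for either case.

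Skeletal muscle genes fell in HDM ear. Dilution of resident tissue by infiltrate or thicker epidermis would lower other resident lists alike, but muscle fell more than the mean of the cartilage, Schwann cell and melanocyte lists, with a difference of -2.0 (95% interval -2.74 to -1.27), which argues against dilution as the whole cause. Genes near background can fall only little. Among genes well above background in sham ear the difference was -1.81 (95% interval -2.57 to -1.06). That rests on 17 of 20 muscle, 7 of 16 cartilage, 3 of 7 Schwann cell and 3 of 8 melanocyte genes. Fa2h, on the Schwann cell list, is also on the ceramide list. With array medians made equal the list median was -2.91, but this moved the median of all rows in ear only from -0.0225 to -0.02, so it was no test. A shift shared by all rows of an array cancels in the difference of -2.0 and is argued against as the whole cause, while scaling that depends on signal level stays open. A different depth or place of the punch and a loss of muscle transcripts also stay open.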

How the results depend on the processing

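The alternatives that left out sham back mice 1 and 2, used the negative control median as a covariate, kept the control rows or counted identical rows once were chosen only after seeing the data. Where a value below moved, the cause was not tested, unless the alternative itself gives it.

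Of 219 results for named genes, 217 kept their direction and side of the threshold with quantile normalization, 217 with equal array medians, 216 with array weights and 218 with the eBayes trend, and those left were weaker. Fewer did with covariates, namely 122 with the muscle and adipocyte lists (92 weaker, 5 reversed), 200 with the hair list (16 weaker, 3 reversed) and 199 with the negative control median (20 weaker). With dim rows left out 192 of 192 did, within 1 tissue 136 of 140, and among sham arrays alone 69 of 69. Over all single arrays left out, 3605 of 3664 did, and 59 were weaker. Calls ranged from 1123 to 1357 higher and 1576 to 1957 lower in back skin, 3291 to 3765 and 2967 to 3666 in ear, 1817 to 2618 for the difference between sites, and 3168 to 3392 and 2906 to 3103 for sham ear against back.

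With equal array medians 2433 rows were higher in back skin. A minimum log2 difference of 1, which can only remove calls, gave 456 and 766 rows (higher and lower) in back skin, 1675 and 1396 in ear, 1497 for the difference and 1187 and 1520 for sham ear against back. Leaving out dim rows gave 10 lists for sham ear against back, with fewer genes per list. With an estimated correlation 0 lists passed in back skin, 0 in ear, 0 for the difference and 3 for sham ear against back, since correlated genes then count for less.

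With muscle and adipocyte lists as covariates, which themselves changed with HDM, 89 rows were higher and 36 lower in back skin, 62 and 1 in ear, 453 differed between sites, and 12 lists passed for that difference. Reversed values were -0.080 for Il33, -1.08 for Il17a and -0.047 for Il6 in ear, and 0.051 for Npas2 and 0.0074 for Ms4a2 in back skin. Reversed list medians were 0.62 for clock genes in back skin, 0.51 for sebaceous, 0.39 for clock, 0.037 for muscle and -0.048 for Schwann cell genes in ear, and 0.11 for muscle in the difference. The mean of the muscle list is itself a covariate here, so its mean effect is removed by construction. The medians of that list are therefore no result.

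With the hair list as a covariate, 838 rows were higher and 1378 lower in sham ear, and 25 lists passed. Reversed there were Cd3e (-0.43), Tnfrsf13c (0.12) and Slc4a1 (1.61), and the lists of cornified envelope (-0.13), ceramide (-0.086), T cell (-0.50), hair (0.31) and melanocyte genes (3.07). The value for the hair list is no result, since its mean is the covariate and its mean effect is removed by construction. That mean also differs strongly between the sites, so the covariate takes up much of the site difference.

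Without sham back mice 1 and 2, 18 lists passed in back skin, and the hair list median reversed to -0.93 there and to 0.44 in the difference. With the negative control median as a covariate 2051 rows were higher and 1578 lower in ear, 452 differed between sites, 1355 were higher and 1346 lower in sham ear, and the cornified envelope median of the difference reversed to 0.42. That median itself set sham ear apart from the other groups, so the covariate may also remove effects of HDM and of site.

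The labels leave open whether back skin and ear samples of an agent with the same number came from 1 animal. They were not treated as such. With mouse number as a block 1964 rows differed between sites, and the correlation within a number was 0.0148. The lists were not run with mouse as a random block, with the eBayes trend or with single arrays left out, and the eosinophil list had no genes left under the dim filter. Signal over background limits the rest, since a row below the negative control median on all arrays of a group gives only a bound.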

Other observations

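Gene families sharing the start of a symbol were tested only after the results were seen, over 232 families and 464 tests, and 0 passed with an estimated correlation. In back skin, 17 of 40 genes of large ribosomal proteins (Rpl) rose and 0 fell, with a median of 0.38 (adjusted p = 1.22e-10, and adjusted p = 0.506 with an estimated correlation). Of 10 Aadacl genes, which encode arylacetamide deacetylase-like enzymes, 7 fell, with a median of -3.60 (adjusted p = 3.09e-09, and adjusted p = 0.287 with an estimated correlation). Of 25 kallikrein-related genes (Klk) 10 rose and 1 fell (adjusted p = 3.09e-09, and adjusted p = 0.233 with an estimated correlation).

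In ear, 33 of 48 genes of the large mitochondrial ribosomal subunit (Mrpl) and 18 of 28 of the small subunit (Mrps) rose, with medians of 0.66 and 0.57 (adjusted p = 3.09e-09 and 2.56e-05, and adjusted p = 0.418 and 0.407 with an estimated correlation). Of the proteasome genes, 9 of 10 Psmb and 10 of 14 Psmd genes rose, with medians of 0.91 and 0.60. Of 358 zinc finger genes (Zfp) 130 fell and 12 rose, with a median of -0.39 (adjusted p = 5.72e-08, and adjusted p = 0.407 with an estimated correlation). The negative control rows fell in ear by a like amount, with a median of -0.32. Of those 5222 rows 491 were called lower and 21 higher. Whether a lower background accounts for the fall of Zfp genes was not tested.

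The test of other splits was chosen before the data were examined. For HDM against sham in back skin 1 of 100 splits, the real one, reached the 3273 calls, and the highest other gave 921. In ear it was 1 of 100 (7076, highest other 5758) and for sham ear against back 1 of 100 (6593, highest other 3107). These counts argue against chance in these comparisons but do not exclude it, since 1 of 100 is the smallest share that 100 splits can give. For the difference between sites it was also 1 of 100 (2251, highest other 3). Those draws break up the HDM effect shared by both sites as well, so they cannot decide whether the effects differ.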
